A study of Mus musculus with 13 samples.

How the data were processed

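Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in C2C12 cells, a mouse myoblast line that forms myotubes in low serum. The labels described 13 samples, and peak lists of 12 libraries were used. The library of the CRISPR control at 48 h was not analysed here, so the wild-type library at 48 h stood in for it. Each condition had 1 library. No test between conditions was therefore run, and every value describes single libraries.

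Peaks were called per library with MACS2 2.1.0 on the mouse build mm9, per the submitters' processing notes. The aligner, the read filters, the control library and the cutoffs were not given in the sources used here, and read depth was unknown. The authors' lists came in 2 formats. The deposited lists of the 6 time course libraries at -24, 0, 6, 12, 24 and 72 h had 5 columns, the last of which was a score with no stated unit and a lowest value of 4.00 to 4.01. The deposited lists of the 6 libraries at 48 h had 10 columns in the order MACS2 writes. These held a score equal to 10 times the −log10 p cut to a whole number, the fold enrichment at the summit, the −log10 p-value, the −log10 q-value and the summit position, as the authors deposited them. The lowest −log10 p was 3.01 to 3.03 in the 4 hotspot lines, 4.13 in the wild-type library and 4.02 in the Myod1 knockout, so the cutoffs of the deposited lists differed. Scores, folds and −log10 values were the authors' own values for each peak and were not compared in size between libraries. They were used within a list, to rank or filter peaks, to rank domains, to weight regions by their wild-type −log10 p, and as percentiles of −log10 p within each hotspot line over the regions shared by the 4 lines. The formats split the libraries as the 48 h time point does, so format and time could not be told apart for the 48 h wild-type library.

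Peaks counted as shared when they overlapped by 1 base. Regions were made by merging overlapping peaks of the libraries compared. In the time course, late-gained regions had a peak at 24, 48 and 72 h and none at -24 and 0 h, early-lost regions had the reverse, and stable regions had a peak in all 7 libraries. To compare the 48 h libraries, the classes were defined again from -24, 0, 24 and 72 h alone. Similarity of 2 lists was the Jaccard index, the shared over the combined covered bases. Domains were made by joining peaks within 12.5 kb, and large domains were those above the point of slope 1 on the plot of the summed width times fold (or score) against rank, with promoters left in. The H3 deletion pattern was a wild-type peak region with a peak in the H1 line and none in the 3 lines in which H3 was deleted. Shares carry 95% Wilson intervals, which cover counting error only, since neighbouring peaks are not independent and no library was repeated. The comparisons, their alternatives and the rule for named regions (the 5 widest of each class on the assembled chromosomes) were fixed before the data were examined. Chromosome shares, late domains, the difference between late-gained and early-lost percentages, and a common −log10 p of at least 4 were added after the data were examined.

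Alternatives were an overlap of 50% of the shorter peak, a q under 0.001 (a score of at least 5 where no q was given), the same number of strongest peaks in each list, merging of peaks within 1 kb, other times to define the classes, width matching in 10 bins, and joining within 5 kb or 1 kb or ranking by width alone for domains. No annotation of mm9 was used here. In all 12 libraries chromosome 1 peaks lay beyond the last chromosome 1 gene of the GRCm38.p6 gene table, so its positions were not used, no gene was named from a position, and the planned gene lists were not run. Coordinates are given in mm9, counted from 1. The overlap code was tested on 20000 simulated regions, where all 1000 late-gained and all 2000 early-lost regions put in were recovered. The simulated peaks of a region always overlapped and none was missed, so this checked the code and not errors of peak calling. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.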

Results

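H3K27ac was profiled in C2C12 cells 24 h before the change to differentiation medium (-24 h), at the change (0 h) and 6, 12, 24, 48 and 72 h after it. A further 5 libraries came from edited lines at 48 h. One line lacked MyoD, the transcription factor encoded by Myod1 that drives muscle differentiation. The other 4 lines carried deletions of regions the submitters call hotspots. The H1 line lacked hotspot H1, the H3 line lacked H3, and the H23 and H34 lines lacked H3 together with H2 or H4. Each condition had 1 library. The lists held 74764 peaks at -24 h, 86465 at 0 h, 82369 at 6 h, 101331 at 12 h, 80069 at 24 h, 71281 in wild-type cells at 48 h and 69251 at 72 h. The Myod1 knockout had 55585 peaks, the fewest of the 12 libraries, and these covered 18.3 Mb against 45.4 Mb in the wild-type library at 48 h. The hotspot lines had 137960 (H1), 103134 (H3), 124609 (H23) and 130473 (H34) peaks, in lists that reached down to a lower −log10 p than the wild-type one. Read depth was unknown.

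The first question was which regions gained or lost acetylation as myoblasts differentiated. Loss from the myoblast stage outnumbered gain, although the definitions were not symmetric. A lost region needed a peak at 2 of the times compared and a gained one at 3. With 48 and 72 h alone asked to agree, 6600 regions were early-lost and 3286 late-gained. Of 133768 regions, 4660 (3.48%, 95% interval 3.39 to 3.58) were early-lost, with a peak at -24 and 0 h and none at 24, 48 and 72 h. Late-gained regions, with the reverse pattern, numbered 1468 (1.10%, 1.04 to 1.15), and 22485 regions (16.8%, 16.6 to 17.0) had a peak at every time. Stable regions had a median width of 1184 bp, against 646 bp for late-gained and 327 bp for early-lost regions. These are widths of merged regions, which depend on the lists required to have a peak. Late-gained regions had to hold a peak of the 48 h list, whose median peak width of 420 bp was the largest of the time course, and early-lost regions could not.

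The widest late-gained region lay on chromosome 15 at 75295952 to 75299716 and first had a peak at 6 h. The next widest lay on chromosome 4 at 123300269 to 123303629, with a first peak at 12 h. The third, on chromosome 15 at 99718880 to 99721601, had its first peak at 24 h. The others were on chromosome 15 at 33354887 to 33357514 and on chromosome 18 at 5665408 to 5668021. All 5 had a peak in the Myod1 knockout and in each hotspot line. The widest early-lost region was on chromosome 17 at 27694360 to 27696849. The others lay on chromosome 9 at 54489377 to 54491413, chromosome 12 at 72662800 to 72664639, chromosome 2 at 28794205 to 28795994 and chromosome 11 at 88402177 to 88403841. All 5 still had a peak at 6 and 12 h and none from 24 h on in the wild-type series.

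The first peaks of gained regions were spread over time. Of 3286 regions with a peak at 48 and 72 h and none at -24 and 0 h, 994 (30.2%) first had a peak at 6 h, 906 (27.6%) at 12 h, 328 (9.98%) at 24 h and 1058 (32.2%) at 48 h. Of 6600 regions lost by 48 and 72 h, the last peak was at 12 h in 2900 (43.9%), at 24 h in 1940 (29.4%), at 0 h in 1195 (18.1%) and at 6 h in 565 (8.56%). The 12 h list was the longest of the time course, with 101331 peaks. Median peak width was lowest at 24 h, at 203 bp, and highest at 48 h, at 420 bp. The shares were not corrected for list length or peak width, so they do not by themselves date a gain or loss. With no replicates, patterns that are neither a lasting gain nor a lasting loss give a background, in which short-lived changes are included. For a peak at 2 of the 5 times -24, 0, 24, 48 and 72 h there were 8 such patterns, the largest with 2108 regions, fewer than the early-lost ones. For a peak at 3 of the 5 there were 8 as well, and 2 of them outnumbered the late-gained regions, with 2637 regions at -24, 0 and 48 h and 1617 at 0, 24 and 72 h. The late-gained count thus did not stand above this background. With peaks within 1 kb merged there were 798 late-gained and 1540 early-lost regions. With 24 and 72 h alone asked to agree, whatever the 48 h library held, there were 3165 and 7297.

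Peak sets drifted apart with time. The Jaccard index with the -24 h library was 0.550 at 0 h, 0.527 at 6 h, 0.478 at 12 h, 0.452 at 24 h and 0.403 at 72 h. The wild-type library at 48 h fell outside this order, at 0.333. It was nearer to the hotspot lines, at 0.403 to 0.449, than to the 72 h library, at 0.312. The formats of these lists also differed, but its index did not follow format throughout. It was 0.279 with the Myod1 knockout, whose list had the same format, and 0.394 with the 6 h library, whose list had the other. The H23 and H34 lines, which share the H3 deletion, had an index of 0.545 with each other, against 0.454 and 0.456 with the H1 line.

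Large stitched domains, built as for super-enhancers, overlapped those of the -24 h library less at 24, 48 and 72 h than at 0 h. The -24 h library had 788 of them, and 79.3% (76.3 to 82.0) overlapped a large domain at 0 h, 68.9% (65.6 to 72.0) at 24 h, 48.4% (44.9 to 51.8) in wild-type cells at 48 h and 57.0% (53.5 to 60.4) at 72 h. In reverse, 78.7% (75.7 to 81.4) of the large domains at 0 h, 67.8% (64.4 to 70.9) at 24 h, 49.1% (45.6 to 52.7) in wild-type cells at 48 h and 67.5% (63.8 to 71.0) of the 655 at 72 h overlapped one at -24 h, with no fall from 24 to 72 h. The 48 h library was lowest of these both ways. Its domains were ranked by width times fold and those of the other times by width times score. Ranking measure and time could therefore not be told apart for it, and ranking by width alone was not run for -24 against 48 h. At 48 h there were 761 large domains in wild-type cells and 683 in the Myod1 knockout, and 50.9% (47.3 to 54.4) of the wild-type ones overlapped a large knockout domain. The shares were 79.8% (76.8 to 82.5) for the H1 line, 78.3% (75.3 to 81.1) for H34, 74.4% (71.2 to 77.3) for H23 and 68.2% (64.8 to 71.4) for H3, lines with 1141, 1152, 1142 and 932 large domains. In reverse, 57.5% (53.8 to 61.2) of the knockout's large domains overlapped a wild-type one, against 50.1% for H1, 48.8% for H34, 46.6% for H23 and 53.8% for H3. The knockout and H3, with the fewest large domains, thus had the lowest shares one way and the highest the other way. Counts of large domains depended on the joining distance (932 in H3, and 1887 when peaks were joined within 1 kb only), and joining within 5 kb removed the difference between H1, at 68.7%, and H3, at 69.3%.

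The Myod1 knockout asked which acetylation depends on MyoD. In that line, 57.5% (57.1 to 57.8) of the 71281 wild-type peaks had no peak, whereas 25.5% (25.2 to 25.9) of the knockout peaks had none in wild-type cells. The loss was far from even over the region classes, here defined without the 48 h libraries. Among regions with a wild-type peak, 811 of 1171 late-gained ones (69.3%, 66.6 to 71.8) had none in the knockout, against 3686 of 20661 stable ones (17.8%, 17.3 to 18.4), a difference of 51.4 percentage points (48.7 to 54.1). Early-lost regions that had a wild-type peak at 48 h lacked it as often, in 1459 of 2105 (69.3%, 67.3 to 71.2). In number, most of the losses in these 3 classes were in stable regions, which were also wider. Stable regions lacked their wild-type peak least often in all 4 hotspot lines as well. Late-gained, early-lost and stable regions lacked it in 6.83%, 23.4% and 1.78% of cases in H1 and 26.9%, 32.5% and 6.84% in H3. The shares were 25.8%, 16.2% and 3.81% in H23 and 24.3%, 14.6% and 2.53% in H34. The unevenness was thus not particular to the knockout, although its shares were higher in each class.

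The 5 widest regions lost in the Myod1 knockout had a peak in the wild-type library and in all 4 hotspot lines, and only 1 of them, on chromosome 11 at 105665039 to 105668892, lacked a peak at -24 h. They included a pair on chromosome 6, at 129164515 to 129170647 and 129178388 to 129184169. The others were on chromosome 11 at 77254211 to 77258753 and chromosome 17 at 32158243 to 32162315. The knockout list was the shortest, and with equal numbers of strongest peaks 49.8% of wild-type peaks lacked a knockout peak. Its target gene could not be checked, since peaks of a histone mark do not show whether Myod1 was disrupted.

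**Figure D1:**
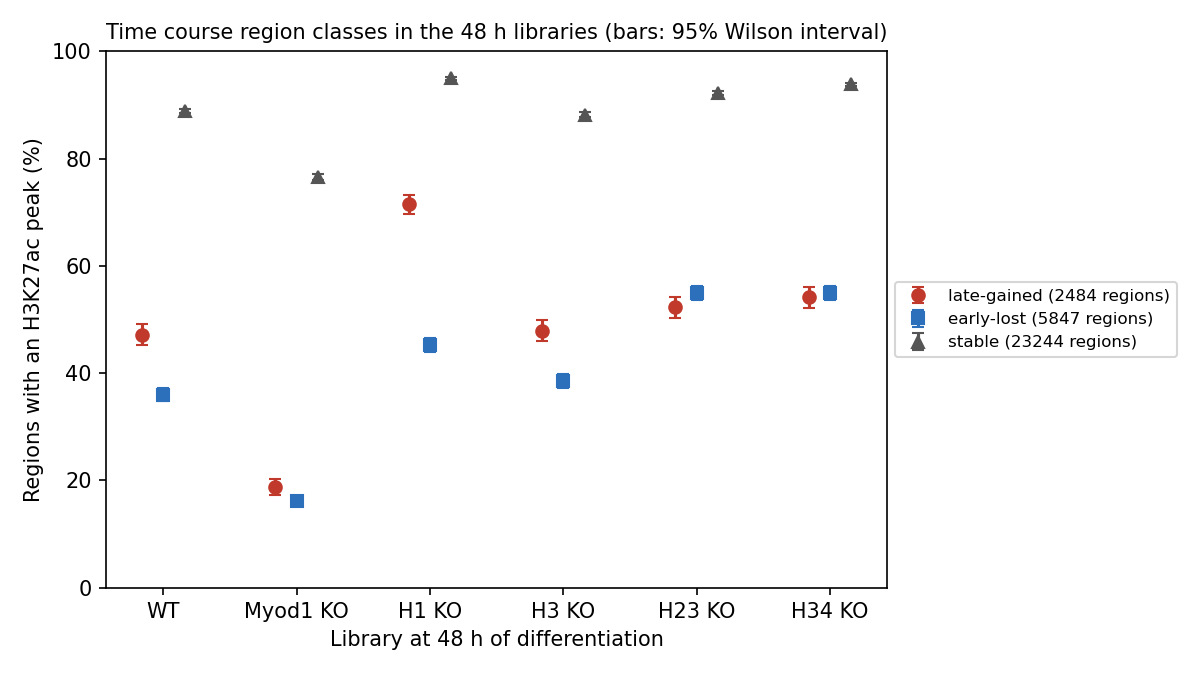
Percentage of late-gained (circles), early-lost (squares) and stable (triangles) regions with an H3K27ac peak in each of the 6 libraries at 48 h, with 95% Wilson intervals. The classes were defined by peaks at -24, 0, 24 and 72 h, on regions merged with the 48 h peaks as well. Late-gained regions stood highest in the H1 line, at 71.5%, and lowest in the Myod1 knockout, at 18.8%.

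The hotspot deletions asked what acetylation is lost when regulatory regions are removed, singly (H1, H3) or in pairs (H23, H34). In each line most wild-type peaks overlapped a peak. Wild-type peaks had no peak in 16.2% (15.9 to 16.4) of cases in the H1 line, 18.0% (17.7 to 18.3) in H34, 18.2% (17.9 to 18.5) in H23 and 26.0% (25.7 to 26.3) in H3, the line with the fewest peaks of the 4. In the other direction, 55.6% of H1, 48.6% of H3, 59.4% of H23 and 56.2% of H34 peaks had no wild-type peak. With equal numbers of strongest peaks the loss was 29.3% for H1, 33.1% for H3, 26.7% for H23 and 29.2% for H34, so the lowest loss was then in H23. Those lists were made equal within each pair. By the Jaccard index of the 55585 strongest peaks of every library, H1 was nearest to wild type, at 0.485. The index was 0.477 for H34, 0.468 for H3 and 0.440 for H23.

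The lines differed more clearly in the time course classes. Late-gained regions had a peak in 71.5% (69.7 to 73.2) of cases in the H1 line, against 47.9% (45.9 to 49.8) in H3, 52.3% (50.4 to 54.3) in H23, 54.1% (52.2 to 56.1) in H34 and 47.1% (45.2 to 49.1) in wild-type cells. None of the 3 lines without H3 thus lay below wild type in the deposited lists, but their lists were longer than the wild-type one. Of the late-gained regions with a wild-type peak, 6.83% had none in H1, 26.9% in H3, 25.8% in H23 and 24.3% in H34. Early-lost regions had a peak in 45.2% (43.9 to 46.5), 38.5% (37.3 to 39.8), 55.0% (53.7 to 56.2) and 54.9% (53.6 to 56.2) in the same order of lines, and in 36.0% (34.8 to 37.2) in wild-type cells. The late-gained percentage thus exceeded the early-lost one by 26.3 points in H1 and 9.37 points in H3, and lay 2.63 points below it in H23 (-2.63) and within 1 point of it in H34 (-0.75). The wild-type library stood at 11.1 points and the Myod1 knockout at 2.65 points. With classes taken from 12 and 24 h the differences were 9.79 points in wild-type cells, 8.85 in H23, 9.30 in H34, 19.2 in H3 and 32.4 in H1. H23 and H34 were then near wild type and H3 above it, so the order of the H3-deleted lines against wild type depended on the times chosen.

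The H3 deletion pattern, a wild-type peak with one in the H1 line and none in the 3 lines without H3, was found in 2687 of 51971 wild-type regions. The 3 other ways to have a peak in 1 line alone, which no shared deletion predicts, gave 225 regions for H3, 725 for H23 and 1044 for H34. The H1 list was the longest of the 4 lines, at 137960 peaks, which favours a peak in that line alone. With equal numbers of strongest peaks the pattern had 2973 regions and the next one-line pattern 1459. With peaks within 1 kb merged the counts were 1229 and 510. The widest regions of the pattern lay on chromosome 16 at 45797195 to 45801256 and on chromosome 13 at 46617481 to 46621318 and 46719611 to 46723123. The others were on chromosome 10 at 69518096 to 69521584 and chromosome 15 at 66606423 to 66609772. None of the 5 had a peak in the Myod1 knockout. A wild-type peak missing in 1 line and present in the other 3 was found in 1602 regions for H1, 2888 for H3, 940 for H23 and 1176 for H34. The 2888 regions missing in the H3 line alone, which a deletion shared with H23 and H34 does not predict, outnumbered the H3 deletion pattern. Each deletion had 1 line and 1 library, so a deletion and other differences of the line could not be separated.

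Late domains were examined after these results were known. They were wild-type domains at 48 h with at least 5 peaks, of which none overlapped a peak at -24 or 0 h and at least 50% overlapped one at 72 h. There were 10 among 4179 domains. Of these, 7 held no wild-type peak with a Myod1 knockout peak, against 384 of the 4169 other domains (9.21%). Of their 60 wild-type peaks, 59 had a peak in the H1 line, 45 in H3, 35 in H23, 31 in H34 and 4 in the Myod1 knockout. Relative to the peaks of all 4179 domains, the share was 75.0% against 77.3% in H3, so that line was not reduced. It was 58.3% against 83.7% in H23, 51.7% against 84.2% in H34, 6.67% against 43.6% in the Myod1 knockout and 98.3% against 86.9% in H1. The 60 peaks include 11 of the chromosome 1 domain described next, which had been inspected before the rule was set. Of these 11, 3 had a peak in H3, 1 in H23 and none in H34, so this domain alone lowered the shares of the 3 lines. With equal numbers of strongest peaks there were 15 late domains, and 6 of them held no such peak in the Myod1 knockout. Late domains were picked for lacking peaks in the -24 and 0 h lists, and the other domains were not matched to them in peak number or strength. These comparisons therefore cannot separate an effect of an edit from a general tendency of such peaks to be missing from a list.

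In the deposited lists, the late domain in which H1 exceeded the H3-deleted lines most spanned 27.4 kb of chromosome 1, at 136172574 to 136199951. It had no peak at -24, 0, 6 and 12 h. Its 11 wild-type peaks overlapped a peak in 3 cases at 24 h and 7 at 72 h. All 11 had a peak in the H1 line, whose peaks covered 58.7% of the domain against 25.4% in wild-type cells. Of the 11, 3 had a peak in H3, 1 in H23, none in H34 and none in the Myod1 knockout. A nearby wild-type peak at 136257733 to 136259349 overlapped a peak in each of the other 11 libraries. The other wild-type peaks drawn around the domain overlapped none in the Myod1 knockout. Those at 136232661 to 136232879 and 136235028 to 136235306 overlapped a peak in the H1 line alone, so the pattern was not confined to the domain. The domain's interval had been inspected before any genome-wide rule was set, because of prior knowledge of where the study's model gene lies, and whether it holds that gene was not checked. Rules tried earlier ranked other domains above it, and 15 of the 4179 domains had an excess of H1 at least as large. With equal numbers of strongest peaks a late domain on chromosome 13 ranked first instead.

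**Figure D2:**
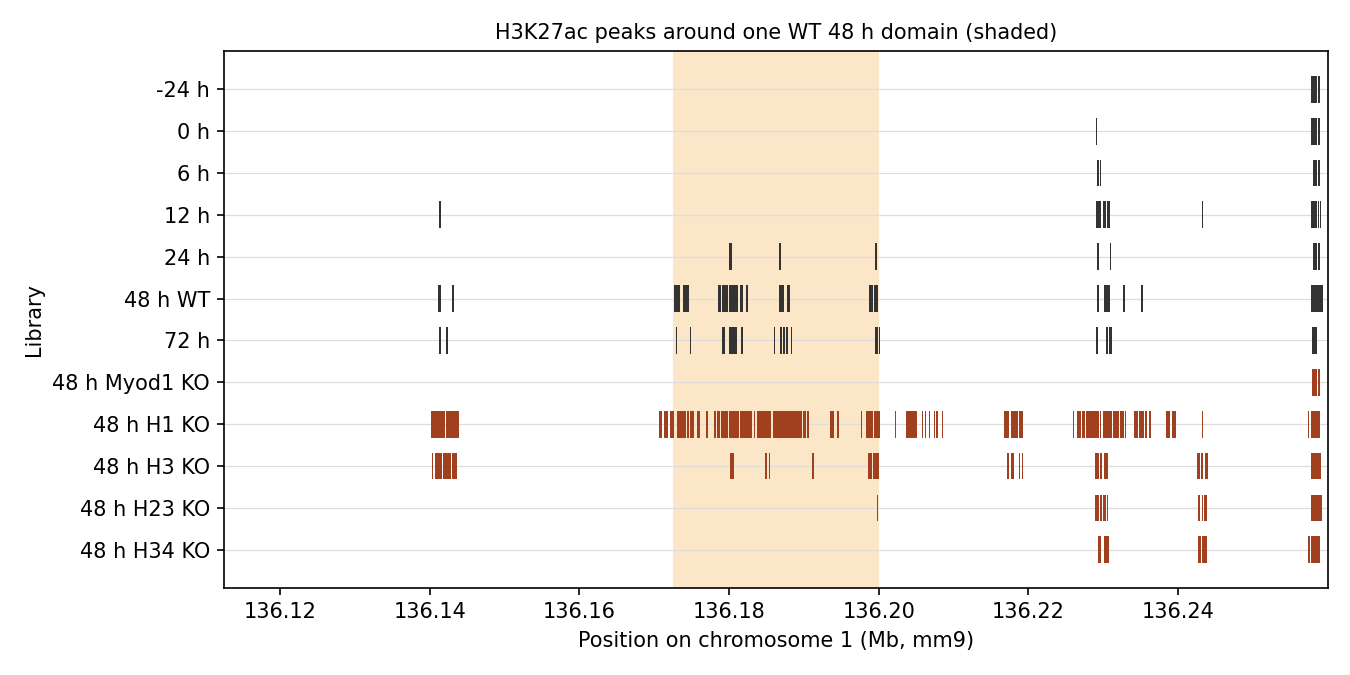
H3K27ac peaks (bars, to scale) of the 12 libraries around the chromosome 1 domain at 136172574 to 136199951 (shaded), with position in Mb on mm9 along the horizontal axis and 1 library per row. Peaks cover 58.7% of the shaded span in the H1 line and are absent from it in the Myod1 knockout and H34 lines.

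The libraries at 48 h differed in how their peaks were spread over chromosomes. Chromosome 14 held 1.66% of the covered bases in the H34 line, against a median of 3.47% over the 12 libraries, a log2 ratio of -1.06. Over the 6 libraries at 48 h the highest and lowest share of a chromosome differed by up to 2.04-fold, and 6 chromosomes exceeded 1.5-fold. In the 6 other time course libraries the highest was 1.41-fold, on the X chromosome, and none exceeded 1.5-fold. This comparison was added after the data were examined.

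**Figure D3:**
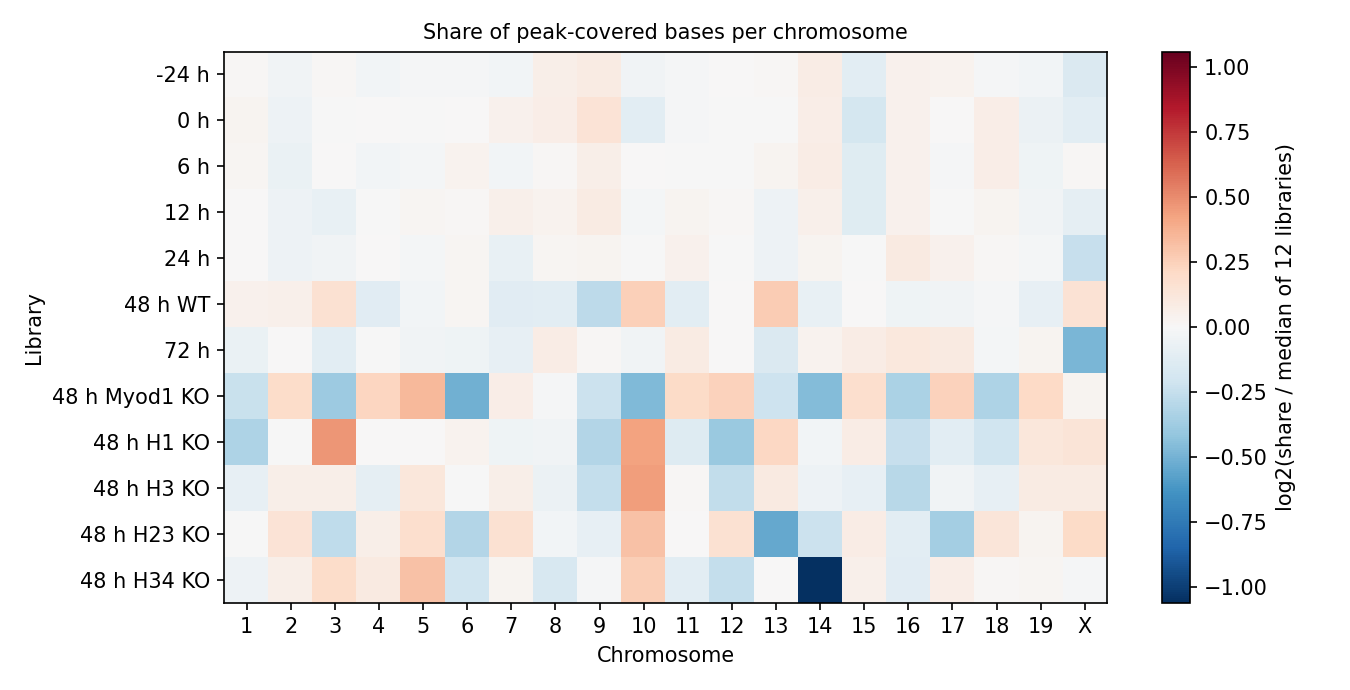
Share of peak-covered bases per chromosome (columns) in each of the 12 libraries (rows), as log2 of the ratio to the median over the libraries. Chromosome 14 of the H34 line is the lowest cell, at -1.06, and the edited lines vary more than the time course libraries other than 48 h.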

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

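The alternatives with a common −log10 p of at least 4, those of the late-gained minus early-lost differences, the late domains and the chromosome share by peak number were chosen after the data were examined. The planned gene lists were not run, since no annotation of mm9 was used. Depth was unknown, so its effect on weak peaks was not tested. There were 182 alternatives over 45 results. For the shares of hotspot line peaks without a wild-type peak and the overlaps of large domains, 39 moved and 2 stayed the same. For the other results 63 moved, 75 stayed the same and 3 changed sign. Only differences could change sign, since counts, shares and Jaccard indices cannot be negative. For the values that moved, the cause was not tested beyond what each setting changes by construction. No paired analysis was possible because each condition had 1 library.

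With peaks within 1 kb merged, late-gained regions numbered 798, early-lost 1540 and the H3 deletion pattern 1229, beside 510 for the next one-line pattern. With 48 and 72 h asked to agree, late-gained regions numbered 3286. With 24 and 72 h they numbered 3165 and early-lost regions 7297. Early-lost outnumbered late-gained regions, and the H3 deletion pattern the other one-line patterns, under every alternative run.

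Wild-type peaks lacking a Myod1 knockout peak came to 59.6% with 50% overlap, 59.4% with q under 0.001, 49.8% with equal numbers and 49.7% with merging. The reverse share was 29.1%, 22.97% and 29.5% for the first 3 of these. Wild-type peaks lacking one in H1, H3, H23 and H34 came to 19.6%, 28.8%, 20.5% and 21.0% with 50% overlap, 19.1%, 27.2%, 19.6% and 19.1% with q under 0.001, 29.3%, 33.1%, 26.7% and 29.2% with equal numbers, and 14.9%, 24.6%, 17.1% and 16.4% with merging. At the common −log10 p they were 17.2% for H1, 18.8% for H23 and 18.3% for H34. H3 was highest in each case.

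The excess of Myod1 knockout loss in late-gained over stable regions was 44.6 points with equal numbers, 54.8 with merging, 46.0 with classes from 12 and 24 h and 45.3 with width matching. With equal numbers the late-gained minus early-lost difference was 8.44 points in wild-type cells, 23.5 in H1, 5.81 in H3, -8.40 in H23 and -4.36 in H34. With merging it was -0.186 in the Myod1 knockout, a change of sign, 22.2 in H1 and -5.76 in H34. With classes from 12 and 24 h it was 9.79 in wild-type cells, 8.54 in the Myod1 knockout, 32.4 in H1 and 19.2 in H3, and it changed sign in H23 (8.85) and H34 (9.30). H1 was highest in each case.

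Large domains joined within 1 kb numbered 1235 at -24 h, 1235 in wild-type cells, 1064 at 72 h, 1887 in H3 and 2239 in H23. Joined within 5 kb, H3 had 1494. With equal numbers the Jaccard index was 0.583 for -24 and 0 h, 0.410 for -24 and 72 h, 0.294 for wild type and Myod1 knockout, and 0.572 for H23 and H34. With q under 0.001 the last pair of values was 0.273 and 0.551. Late domains numbered 30 with at least 4 peaks, 18 of them without a Myod1 knockout peak, and 17 with joining within 5 kb, 9 of them without one. With equal numbers of peaks there were 15, of which 6 had none, and another domain, on chromosome 13, led the late domains in H1 excess. By peak number the chromosome 14 share of H34 was 0.583 of the median library.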

Other observations

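A peak at 6 and 12 h only, with none at the other 5 times, was found in 1797 of the 133768 regions, with a median width of 246 bp. A peak in 1 library alone was found in 58285 regions, and without replicates short-lived acetylation and calling noise were not separated. The loss pair on chromosome 6 lay in a stretch of 352.2 kb with no Myod1 knockout peak at all, in which the wild-type library at 48 h had 15 peaks and the -24 h library 19. In 120 gaps between neighbouring knockout peaks there were at least 15 wild-type peaks, so the stretch was not exceptional in that respect.

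The tests of the H3 hotspot, of a loss that picks late-gained regions and of weighted early-lost regions were chosen after their results were seen, and the patterns themselves were found in these data.

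Fewer chromosome 14 peaks were called in the H34 line. With equal numbers of strongest peaks the chromosome 14 share was 0.642 of the mean of the other 3 lines, which argues against cutoff or list length. It was lower than in each other line in 13 of 13 windows of 10 Mb (100%), which argues against a change at a few loci. Over regions with a peak in all 4 lines, those on chromosome 14 had a median within-library percentile of -log10 p of 28.5 in H34, against 50.03 to 56.4 in the others, so a whole-chromosome difference of the clone, such as a lost copy, is a candidate explanation. Copy number was not measured.

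Late-gained regions exceeded early-lost ones in the H1 line by more than in the H3-deleted lines. The H1 difference was above all 3 of them on 20 of 20 chromosomes, which argues against chromosome content of the clones. With equal numbers of strongest peaks it exceeded the highest of them by 17.65 points, which argues against cutoff or list length. The H3 line differed from the wild-type library by only -1.77 points, and lay above it (19.2 against 9.79) with classes from 12 and 24 h, so loss of the H3 hotspot cannot be told apart from a high value in the H1 line alone. How far each culture had differentiated was not tested and stays open as well.

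Wild-type peaks were missing from the Myod1 knockout more often in late-gained than in stable regions. After stable regions were weighted to the wild-type width and -log10 p of the late-gained ones, a difference of 38.6 points was left, so weaker and narrower peaks do not account for all of it. The loss was larger in late-gained regions on 20 of 20 chromosomes, which argues against an uneven spread of the classes over chromosomes as its source. Stable regions had stronger wild-type peaks, with a median -log10 p of 26.5 against 12.8. The count therefore does not test whether a changed copy number lowered calls within a chromosome. Late-gained and early-lost regions lost their peaks equally often, with a difference of -0.054 points. Early-lost regions exceeded stable ones weighted to them in the same way by 35.9 points. The early-lost regions compared had a wild-type peak although their class requires none at the late times, a pattern counted above as background. The equal rate therefore cannot decide whether the loss picks late-gained regions. Stable regions lacked their wild-type peak least often in every hotspot line too. In H3 the late-gained, early-lost and stable shares were 26.9%, 32.5% and 6.84%, and in H34 24.3%, 14.6% and 2.53%. The excess over stable regions was thus not particular to the knockout, although its shares were higher in each class. A hypothesis left by these values is that peaks of regions variable over time may be missing more often from any list, edited or not. The wild-type library itself had a peak in 47.1% of late-gained and 36.0% of early-lost regions, against 88.9% of stable ones. A technical difference of the knockout library other than those tested stays open.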
